A study of Arabidopsis thaliana with 16 samples.

How the data were processed

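The deposited values are MAS5 signal intensities on a linear scale, which the submitters' processing notes attribute to GCOS and MAS5 without stating versions. Each array had been scaled by the submitters so that its trimmed mean signal, leaving out 2% at each end, equalled 100.01. The values were used as deposited, log2-transformed without a pseudocount, and no further scaling between arrays was applied.

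The ATH1 array held 22810 probe sets, of which 64 were controls and were left out. A probe set was tested if its signal exceeded its array's 35th percentile on at least 2 of the 16 arrays. That percentile lay between 12.43 and 18.58 signal units, and 18237 of the 22746 non-control probe sets passed. The deposit gave no detection calls, so this percentile also served as the floor for fold changes. Where every array of the dimmer group was at or below its 35th percentile, the fold is given as a lower bound, the brighter group's mean against the dim arrays' percentile. This floor for folds was chosen after the data were seen. No fold is given where both groups were at or below it.

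Probe sets were named from the annotation table of the array. Of the non-control probe sets, 13513 matched 1 gene, 503 matched several genes and 8730 had no gene name. Among the probe sets tested, these numbers were 10382, 360 and 7495. The named probe sets covered 13286 distinct loci, and the genome annotation (TAIR10.1) was used for names only. For a gene with several probe sets, the one with the highest mean log2 signal over all arrays stood for the gene. Of the 100 genes with several tested probe sets, 1 had probe sets called in opposite directions after 6 h of light in the apex, and 0 had such calls in the other limma contrasts.

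The model was fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 10 groups and no block for replicate numbers. The spread came from the 6 groups with 2 arrays, with 6 residual degrees of freedom. Variances were moderated with an intensity trend (eBayes with trend, prior degrees of freedom 7.618). Each limma p-value is two-sided and was adjusted by the Benjamini-Hochberg method over the probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. The 4 groups with 1 array each (2, 24, 48 and 72 h of light) were assumed to vary like the replicated groups. The contrast called late light averages the 3 group means at 24, 48 and 72 h.

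Gene lists were tested with limma's camera, two-sided, against all other tested probe sets, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 23 lists with at least 3 members. The test was repeated with the correlation estimated from the residuals. That version also takes its p-values from 6 residual degrees of freedom, so it can lose calls where genes are not correlated. Of the 25 lists fixed in advance, 9 could be tested. They covered flavonoid and phenylpropanoid synthesis, photosynthesis, chlorophyll synthesis, cytosolic ribosomal proteins, the nucleolus and ribosome assembly, mitosis and cytokinesis, auxin response, the leaf primordium, and stomata and trichomes. A list gene counted as measured only where a tested probe set matched it alone in the annotation used. This left 3 of 19 genes on the flavonoid list and 6 of 34 on the photosynthesis list. Genes left out may still lie on the array under unnamed or shared probe sets. A further 11 lists had fewer than 3 measured members and were read gene by gene, and 5 had no measured member. Another 14 lists were added after the probe annotation had been seen but before any comparison was made. They were the whole family of cytosolic ribosomal proteins, an extended nucleolus list, plastid ribosomal proteins encoded in the nucleus, an extended list of nuclear photosynthesis genes, core histones, extended lists for DNA replication and mitosis, the genes of the chloroplast genome, expansins with xyloglucan endotransglucosylases, tubulins, UDP-glycosyltransferases, SWEET sugar transporters, tau-class glutathione transferases and autophagy. The extended lists share members with the fixed lists on the same subject, so their calls are not independent.

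The genes named were set by a rule. For each of the main contrasts it took the 6 largest rises and the 6 largest falls among probe sets that were called, matched 1 gene, lay above the 35th percentile on every array of at least 1 compared group, and moved the same way in every pairing of arrays across the groups. For differences between tissues in the light response it took the largest differences without the pairing condition. It added up to 4 members of each list with the smallest adjusted p, and it allowed list members that did not pass to be named with their values. For single arrays, the genes named are members of the lists or of the late contrast. The reference genes chosen in advance (HY5, CHS, CAB2, STM, ANT, CYCB1;1 and PHYA) had no probe set matched to them alone, so none has a value. The groups, contrasts, filter, tests, fixed lists, naming rule and most alternatives were set before the data were examined.

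The procedure was tested on simulated data with 200 changed probe sets among the 18237. For a contrast of 2 against 2 apex arrays it recovered 10.4% of changes of 1 log2 unit, 46.3% of 2 units and 72.7% of 3 units. Its 6 false calls were 6.5% of all calls. For the difference between tissues it recovered 4.5%, 14.9% and 54.5%, with 1 false call. For the single 2 h array it recovered 0%, 32.8% and 62.1%, with 8.7% of calls false. The 200 changes are fewer than the 1974 calls after 1 h in the apex, so these shares need not hold for the data. All groups were simulated with equal spread, so that assumption was not tested. Among 23 simulated lists, the 1 list of 20 members shifted by 0.8 log2 units was called by camera, and 0 of the unshifted lists were. The simulated probe sets varied independently of each other. The simulation therefore does not test how camera behaves with correlated genes, and the estimated correlation was 0.2968 in the ribosomal family and 0.6236 among chloroplast genome transcripts. In some lists it was below 0, at -0.1601 for flavonoid synthesis and -0.1453 for tubulins.

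Alternatives covered quantile normalization, median centring, log2(value + 16), raising dim values to the array's 35th percentile, no filter and a filter at the 50th percentile, a variance prior without trend, arrays of the compared tissue alone, a replicate block, a 2-fold minimum, and leaving out each array in turn. Leaving out both arrays that stood apart was added after seeing the data. Raising dim values, and leaving out single arrays in the list tests, were also not planned in advance.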

Results

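Transcript levels were measured in dissected tissue of dark-grown Arabidopsis thaliana seedlings (Landsberg erecta) before and after a move to light, on 16 Affymetrix ATH1 arrays. Stratified seeds received 30 min of light at 100 µmol m-2 s-1, and seedlings then grew for 3 days in darkness at 21 °C. After harvest, seedlings were stored in RNAlater and either the shoot apex (the meristem region between the cotyledon bases) or the cotyledon blade was cut out, with 1 tissue taken per seedling. Each sample pooled about 1500 to more than 4000 seedlings from several plates and experiments. The apex was sampled in the dark (2 arrays), after 1 h (2), 2 h (1), 6 h (2), 24 h (1), 48 h (1) and 72 h (1) of light. The cotyledon was sampled in the dark, after 1 h and after 6 h, with 2 arrays each. The series concerns how photoreceptors govern the meristem of the shoot and the start of new leaves, and the comparisons ask which transcripts responded to light in each tissue and whether the tissues differed. All dark samples were taken after the 3 days of darkness, and no seedlings kept dark for longer were sampled. A change after light therefore cannot be told apart from a change with age or time of day.

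The number of arrays limits the precision of every value. The median standard error of a log2 change was 0.42 for 2 arrays against 2 and 0.59 for a difference between tissues in the light response. Values are log2 changes ± SE from the limma fit unless a signal is named, and p-values measure only the spread between these samples. Where a group lay at or below the floor, the array's 35th percentile, on every array, folds are bounds, and where it did so on some arrays, a called change stands beside its value with dim signals raised to the floor. Correlations between replicates across probe sets ran from 0.883 to 0.926. Of 503 calls among list members in the light and tissue comparisons, 500 moved the same way in every pairing of arrays, the exceptions being ycf4, cemA and rpl33 in the apex after 6 h.

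The arrays differed in signs of RNA quality. The ratio of 3' to 5' signal for the GAPDH control was 5.40 in apex 6 h replicate 2 and between 0.83 and 1.85 on the other apex arrays, and it was 1.73 to 4.72 on the cotyledon arrays. The actin ratio was 30.4 in apex 6 h replicate 2. Apex dark replicate 2 had the lowest mean correlation with arrays of other groups, 0.786, close to the 0.789 of the 72 h array. Its correlation with its own replicate was 0.896, above the 0.883 of the apex 6 h pair. Median signals ranged from 25.2 to 38.1.

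**Figure D1:**
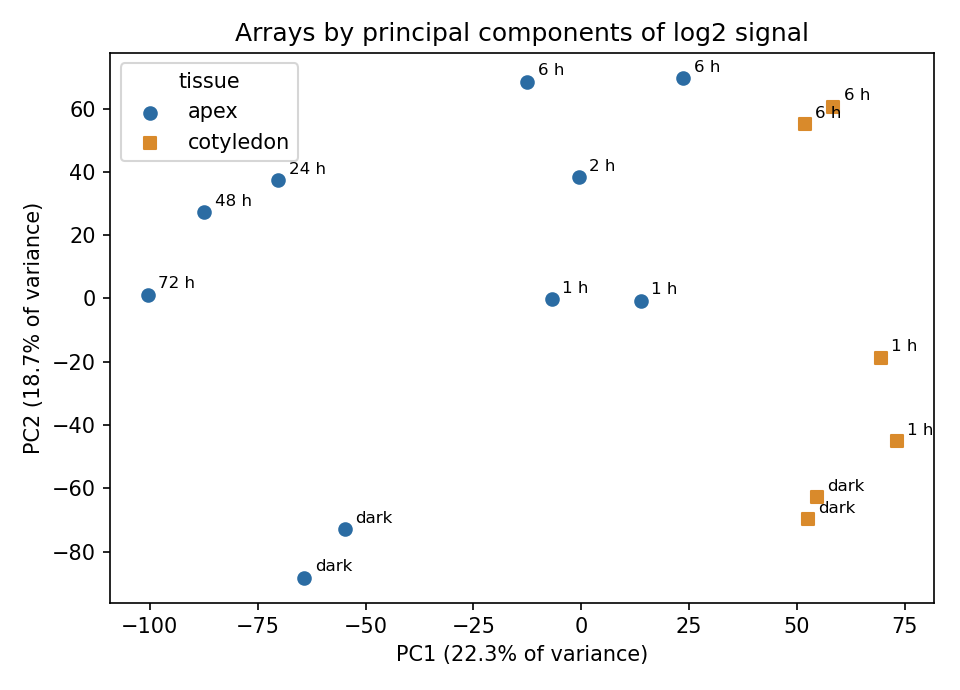
Principal components of log2 signal over 18237 probe sets, with 1 point per array, colours for tissue and labels for hours of light. The first component on the x axis held 22.3% of the variance and the second on the y axis 18.7%, and dark arrays of both tissues lie at the lower end of the second.

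In the apex, some flavonoid genes were higher after 1 h of light and some auxin-response and autophagy genes lower, while no list was called with an estimated correlation. AT1G06000, which encodes a flavonol rhamnosyltransferase, was at least 26.3-fold higher than in the dark (4.72 with dim values raised, adjusted p = 1.47e-08, n = 2 arrays per group). AT3G52740, which encodes an inhibitor of cryptochromes, was at least 11.8-fold higher, and the cytochrome c gene CYTC-2 (AT4G10040) at least 19.8-fold. The thionin gene THI2.2 (AT5G36910) rose by 5.16 ± 0.48 (4.85 with dim values raised), and AT5G48490, which encodes a lipid-transfer protein, by 5.14 ± 0.63. AT2G32150 fell from a signal of 4244 ± 1610 (SD) to 54.9 ± 33.9, a change of -6.37 ± 0.80, and AT2G20670 fell from 1997 ± 318 to 60.9 ± 16.8. AT3G20340 was at least 21.7-fold lower and AT5G02580 at least 17.8-fold lower.

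Among regulators, HYH (AT3G17609), a transcription factor related to HY5, rose by 2.86 ± 0.36 (adjusted p = 0.000223), and the clock gene GI (AT1G22770) by 1.94 ± 0.23 (adjusted p = 0.000131). Of the 3 measured flavonoid genes, 2 rose and 2 passed when adjusted over the list alone. UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, rose by 4.69 ± 0.35, UGT78D1 (AT1G30530) was at least 6.47-fold higher, and dihydroflavonol reductase DFR (AT5G42800) measured -0.88 and was not called. The list median was 3.06 (adjusted p = 0.0114; adjusted p = 0.104 with an estimated correlation). Of 5 auxin-response genes, 3 fell, and 4 when adjusted over the list alone, with a median of -1.52 (adjusted p = 0.00201; adjusted p = 0.104 with an estimated correlation). HAT2 (AT5G47370), an auxin-inducible homeodomain gene, fell by 2.12 ± 0.36. IAA29 (AT4G32280), an auxin-response repressor on the list of dark- and shade-expressed genes, fell by 3.01 ± 0.51, and the other gene of that list, FHL, measured -0.98 and was not called. Of 8 autophagy genes, 5 fell, with a median of -1.71 (adjusted p = 1.45e-05; adjusted p = 0.104 with an estimated correlation). Among them were ATG8E (AT2G45170) at -2.52 ± 0.29, ATG8B (AT4G04620) at -2.26 and ATG8F (AT4G16520) at -2.09, all coding for the ubiquitin-like protein of autophagosomes.

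Some genes of protein synthesis and cell division were higher after 1 h in the apex, and the calls of their lists were all lost with an estimated correlation. In the whole family of cytosolic ribosomal proteins, 37 of 113 genes rose and 0 fell by the limma test, with a median of 0.78 (adjusted p = 1.53e-18; adjusted p = 0.207 with an estimated correlation). Of the 4 genes on the fixed ribosomal list, 1 rose, and 2 when adjusted over the list alone. That list's median was 0.65 (adjusted p = 0.0399; adjusted p = 0.462 with an estimated correlation), and leaving out either dark apex array or apex 1 h replicate 2 ended the call (highest adjusted p = 0.121). Of the 3 genes of mitosis and cytokinesis, 2 rose, the same number when adjusted over the list alone, with a median of 1.195 (adjusted p = 0.0131; adjusted p = 0.104 with an estimated correlation). In the extended mitosis list, 5 of 11 rose, with a median of 0.89 (adjusted p = 0.000364; adjusted p = 0.104 with an estimated correlation), including the spindle checkpoint gene BUB3.2 (AT1G49910), which was at least 2.36-fold higher. The Aurora kinase AUR1 (AT4G32830) rose by 1.195 ± 0.25, a call lost without apex dark replicate 2 or either 1 h array (highest adjusted p = 0.0617). The histone H2B gene HTB1 (AT1G07790) rose by 1.87 ± 0.31 (adjusted p = 0.00159), the single call among 8 core histones. The histone median was 0.66 (adjusted p = 0.0135; adjusted p = 0.104 with an estimated correlation), and it was not called without apex 1 h replicate 2 (adjusted p = 0.105).

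Further list calls after 1 h in the apex depended on single arrays. The extended nucleolus list had 2 of 22 genes higher and a median of 0.53 (adjusted p = 0.0279; adjusted p = 0.549 with an estimated correlation), lost without apex dark replicate 1 or apex 1 h replicate 2 (highest adjusted p = 0.114). The 9 plastid ribosomal protein genes had a median of 0.44 (adjusted p = 0.0338; adjusted p = 0.549 with an estimated correlation), lost without apex dark replicate 2 or apex 1 h replicate 2 (highest adjusted p = 0.121). Of 5 chlorophyll synthesis genes, 3 rose, also 3 when adjusted over the list alone, with a median of 0.84 (adjusted p = 0.0759). The fixed nucleolus list had 1 of 4 higher, also 1 adjusted over the list alone, and was not called (adjusted p = 0.0966). The fixed lists for photosynthesis (adjusted p = 0.644), the leaf primordium (adjusted p = 0.327) and stomata (adjusted p = 0.822) had 0 calls by limma, and 0 adjusted over the list alone. The 69 chloroplast genome transcripts had 0 calls by limma and a median of -0.73 (adjusted p = 0.000908; adjusted p = 0.636 with an estimated correlation). Their median was 0.02 without apex dark replicate 2 and the call was also lost without apex 1 h replicate 2.

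In total, 1974 of 18237 probe sets were called after 1 h in the apex, 1038 higher and 936 lower, and 1744 of these changed at least 2-fold. Without 1 array at a time the count fell to 822 (apex dark replicate 2), 1008 (apex 1 h replicate 1) or 722 (apex 1 h replicate 2), the last with 340 higher and 382 lower, and a variance prior without trend gave 1016.

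After 6 h in the apex, most measured flavonoid, ribosomal and mitotic genes were higher and most measured auxin-response and autophagy genes lower. No list was called with an estimated correlation. THI2.2 was 7.88 ± 0.48 above the dark level (adjusted p = 3.47e-07, n = 2 arrays per group; 7.57 with dim values raised). RR16 (AT2G40670), a cytokinin-response regulator, was at least 9.52-fold higher, MSRB6 (AT4G04840), a methionine sulfoxide reductase, at least 59.4-fold, and the glutaredoxin gene AT2G30540 at least 12.4-fold. AT1G60590, coding for a pectin lyase-like protein, was at least 10.7-fold higher and AT5G48490 rose by 6.60 ± 0.63. AT1G19530 was at least 55.7-fold lower, the linker histone gene HIS1-3 (AT2G18050) at least 8.36-fold lower, AT5G60760 at least 8.41-fold lower, and AT4G25580 fell by 5.76 ± 0.40, or by 5.47 with dim values raised.

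All 3 flavonoid genes rose after 6 h, also all 3 when adjusted over the list alone, with a median of 4.04 (adjusted p = 0.00011; adjusted p = 0.0874 with an estimated correlation). DFR rose by 4.93 ± 0.53, from a signal of 24.3 ± 13.6 (SD) to 677.5 ± 43.3, and UGT78D2 rose by 4.04 ± 0.35. HYH stayed raised at 2.60, while GI measured 0.03 and was not called. In the ribosomal family, 79 of 113 rose and 0 fell by the limma test, with a median of 1.15 (adjusted p = 1.38e-25; adjusted p = 0.14 with an estimated correlation), for example AT4G13170 by 2.57 and AT2G20450 by 2.21. Of the 4 fixed ribosomal genes, 3 rose, and 3 adjusted over the list alone (median 1.16, adjusted p = 0.0187; adjusted p = 0.38 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.104) and without apex 6 h replicate 2 (adjusted p = 0.0886). All 3 fixed mitosis genes rose, also adjusted over the list alone, with a median of 1.99 (adjusted p = 0.00289; adjusted p = 0.0874 with an estimated correlation), among them AUR1 by 1.99 ± 0.25 and AUR2 (AT2G25880) by 2.94 ± 0.41. In the extended mitosis list 7 of 11 rose (median 1.82, adjusted p = 0.00011; adjusted p = 0.0874 with an estimated correlation). Of 8 core histones, 5 rose (median 1.16, adjusted p = 0.00289; adjusted p = 0.0874 with an estimated correlation).

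Photosynthesis calls in the apex after 6 h depended on scaling. Of the 6 fixed photosynthesis genes, 4 rose after 6 h in the apex, and 5 adjusted over the list alone, with a median of 1.04 (adjusted p = 0.00886; adjusted p = 0.38 with an estimated correlation). Quantile normalization lowered that median to 0.68 and ended the call (adjusted p = 0.095). The extended list had 6 of 11 higher and a median of 1.00 (adjusted p = 0.00348; adjusted p = 0.439 with an estimated correlation), not called after quantile normalization (adjusted p = 0.105). PSAN (AT5G64040), a photosystem I subunit, rose by 1.78 ± 0.27. Plastid ribosomal proteins had 2 of 9 higher and a median of 0.52 (adjusted p = 0.0132; adjusted p = 0.455 with an estimated correlation), which quantile normalization lowered to 0.05 (adjusted p = 0.266) and the loss of apex 6 h replicate 2 also ended (adjusted p = 0.056). Of the chlorophyll synthesis genes 3 of 5 rose and 1 fell, also 3 and 1 adjusted over the list alone, and the list was not called (adjusted p = 0.0748). Magnesium chelatase CHLI2 (AT5G45930) rose by 1.89 and protochlorophyllide oxidoreductase PORB (AT4G27440) fell by 2.01 ± 0.31.

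Auxin-response genes were lower after 6 h in the apex, with 4 of 5 called, also 4 when adjusted over the list alone, and a median of -2.02 (adjusted p = 0.00871; adjusted p = 0.129 with an estimated correlation). IAA20 (AT2G46990) fell by 2.02 and HAT2 by 2.09. Of 8 autophagy genes 6 fell (median -1.36, adjusted p = 0.000658; adjusted p = 0.192 with an estimated correlation). Isocitrate lyase ICL (AT3G21720), an enzyme of the glyoxylate cycle and the single measured gene of lipid mobilisation, fell by 1.85. Of the leaf primordium genes 1 of 4 rose, with 1 higher and 1 lower adjusted over the list alone, and the list was not called (adjusted p = 0.719). The gene that rose was YAB5 (AT2G26580), a YABBY transcription factor of lateral organs, by 1.27 ± 0.30 (adjusted p = 0.00678), a call lost without apex dark replicate 2 (1.02). Of 4 stomata and trichome genes, 1 was higher, also 1 adjusted over the list alone, and the list was not called (adjusted p = 0.72). The extended nucleolus list had 6 genes higher and 1 lower of 22 (median 0.33, adjusted p = 0.0235; adjusted p = 0.532 with an estimated correlation), lost without apex dark replicate 1 or apex 6 h replicate 1 (highest adjusted p = 0.244). The fixed nucleolus list had 2 of 4 higher, also 2 adjusted over the list alone (adjusted p = 0.0521).

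Chloroplast genome transcripts were lower in the apex after 6 h, with 16 of 69 called and a median of -1.43 (adjusted p = 8.58e-07; adjusted p = 0.506 with an estimated correlation). These transcripts moved with the arrays that stood apart. Relative to the dark mean, their median was -0.40 in apex 6 h replicate 1 and -2.63 in replicate 2, the array with the GAPDH ratio of 5.40, and the dark arrays themselves lay at -0.73 and 0.73. Without apex 6 h replicate 2 the median change was -0.40 and not called (adjusted p = 0.0643).

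After 6 h in the apex 4594 probe sets were called, 2248 higher and 2346 lower, and 3984 changed at least 2-fold. The count was 2846 without apex dark replicate 2 and 2316 without both arrays that stood apart. Median centring shifted the median of all probe sets by 0.15 and moved the share of calls that were higher from 48.9% to 58%.

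**Figure D2:**
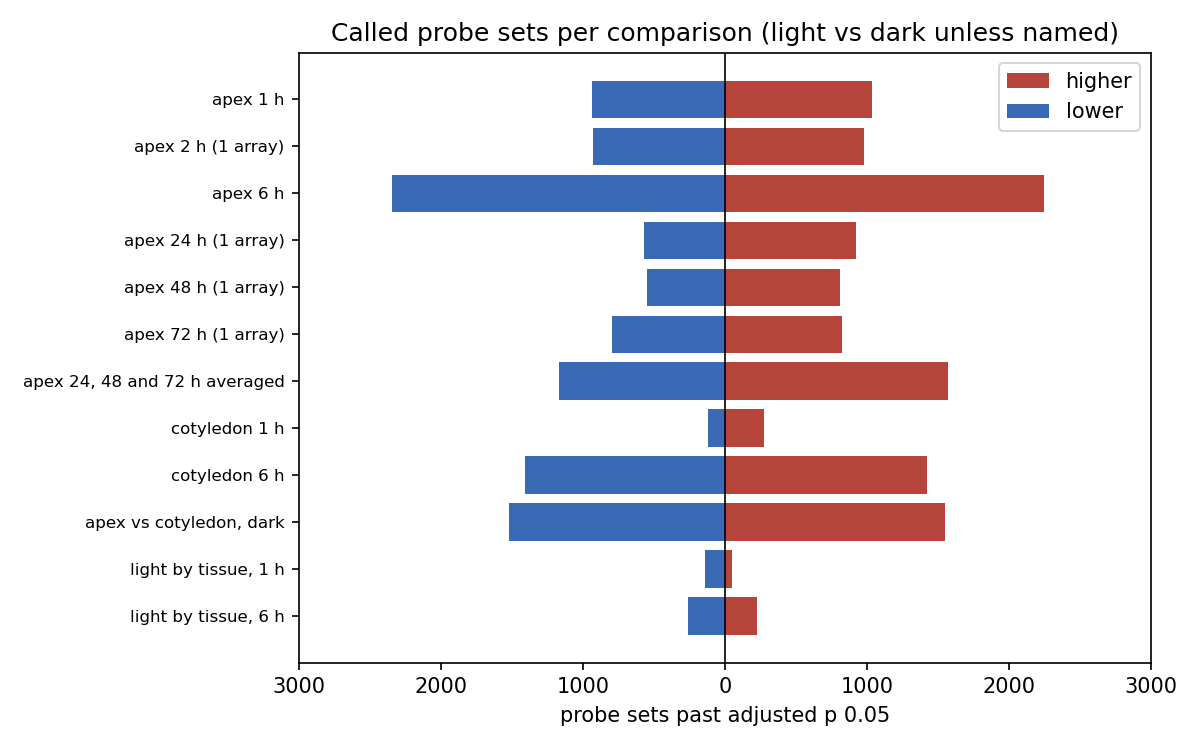
Bars give the number of probe sets (x axis) called higher, to the right, and lower, to the left, in each contrast (limma, adjusted p under 0.05), with 1974 calls in the apex and 399 in the cotyledon after 1 h. After 6 h the counts were 4594 and 2829.

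In the cotyledon, HYH, GI and UGT78D2 were higher and HAT2 lower after 1 h of light than in the dark. AT3G21670, which encodes a nitrate transporter, was at least 30.8-fold higher (4.94 with dim values raised, adjusted p = 7.47e-07, n = 2 arrays per group). AT3G52740 was at least 12.2-fold higher, AT3G57020 at least 4.58-fold, and AT5G42760 rose by 4.18 ± 0.36. GH3.3 (AT2G23170), an auxin-conjugating enzyme gene, was at least 3.11-fold lower, and AT4G35720 fell by 4.04 ± 0.58. HYH rose by 2.76, GI by 2.47 ± 0.23 and UGT78D2 by 3.94 ± 0.35.

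Of the 5 auxin-response genes in the cotyledon, 2 fell after 1 h, and 3 adjusted over the list alone, with a median of -0.92 (adjusted p = 0.000908; adjusted p = 0.156 with an estimated correlation). HAT2 fell by 3.51 ± 0.36 (adjusted p = 5.37e-05), or by 3.49 with dim values raised. Of the 3 flavonoid genes 1 rose, and adjusted over the list alone 2 were higher and 1 lower, with a median of 1.30 (adjusted p = 0.045; adjusted p = 0.308 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.0584). That median was 2.03 without cotyledon 1 h replicate 1 and 0.57 without replicate 2. In the ribosomal family 0 of 113 genes were called by limma, and the median was -0.08 and the mean -0.07 while the test pointed up without a call (adjusted p = 0.812). Core histones, the extended DNA replication list and the expansin list also had a median and mean below 0 and a test direction above 0, all without a call. Autophagy genes had 0 calls by limma and a median of -0.30 (adjusted p = 0.342).

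In the cotyledon 399 probe sets were called after 1 h, 276 higher and 123 lower, against 2135 at an unadjusted p under 0.05. The count was 202 without cotyledon dark replicate 1, 166 higher and 36 lower, 354 without cotyledon 1 h replicate 2, 189 higher and 165 lower, and 190 with a variance prior without trend.

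After 6 h in the cotyledon, some genes of ribosome assembly, mitosis and histones were higher and some autophagy genes lower, while no list was called with an estimated correlation. AT1G60590 was at least 24.7-fold higher (adjusted p = 6.87e-05 with dim values raised, n = 2 arrays per group), the lipid-transfer protein gene AT5G55450 at least 13.9-fold, and AT3G21670 at least 36.7-fold. AT3G57020 was at least 21.5-fold higher, AT2G30540 at least 14-fold and the lipase gene AT4G28780 at least 10.9-fold. The myb-type gene MYBC1 (AT2G40970) was at least 9.25-fold lower, AT5G02580 at least 32.2-fold, AT2G37670 at least 8.01-fold and AT1G19530 at least 7.35-fold. The expansin gene EXPA8 (AT2G40610) was at least 5.53-fold higher.

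The extended nucleolus list had 8 of 22 genes higher after 6 h in the cotyledon, with a median of 1.07 (adjusted p = 5.15e-06; adjusted p = 0.22 with an estimated correlation). Examples are AT1G52930, a ribosome assembly gene, at 2.42 ± 0.32, AT3G22660 at 2.83 (2.71 with dim values raised) and YAO (AT4G05410) at 1.91. Of the 4 fixed nucleolus genes 1 rose, and 4 when adjusted over the list alone (median 1.26, adjusted p = 0.0028; adjusted p = 0.164 with an estimated correlation). In the ribosomal family 28 of 113 rose (median 0.54, adjusted p = 3.52e-11; adjusted p = 0.268 with an estimated correlation). The fixed ribosomal list had 1 of 4 higher, and 3 adjusted over the list alone (median 0.76, adjusted p = 0.028; adjusted p = 0.319 with an estimated correlation), lost with quantile normalization (adjusted p = 0.13) and without cotyledon dark replicate 1 or cotyledon 6 h replicate 1 (highest adjusted p = 0.0766). Of the 3 fixed mitosis genes 2 rose, also 2 adjusted over the list alone (median 1.00, adjusted p = 0.0157; adjusted p = 0.142 with an estimated correlation), and the extended list had 4 of 11 higher (median 1.28, and 0.79 without cotyledon dark replicate 2; adjusted p = 0.000402; adjusted p = 0.142 with an estimated correlation). AUR2 rose by 2.39 and the kinetochore gene AT3G54630 was at least 6.35-fold higher. Of 8 histones 4 rose (median 1.21, adjusted p = 0.000181; adjusted p = 0.108 with an estimated correlation).

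Of the 6 photosynthesis genes 1 rose after 6 h in the cotyledon, also 1 adjusted over the list alone (median 0.54, adjusted p = 0.00779; adjusted p = 0.301 with an estimated correlation). It was the antenna gene LHCB4.2 (AT3G08940), which rose by 2.31 ± 0.29. The extended photosynthesis list had 2 of 11 higher (median 0.58, adjusted p = 0.0028; adjusted p = 0.333 with an estimated correlation). Of the 3 flavonoid genes 2 rose, also 2 adjusted over the list alone (median 1.42, adjusted p = 0.0129; adjusted p = 0.142 with an estimated correlation). Of the 5 auxin-response genes 3 fell, also 3 adjusted over the list alone (median -1.45, adjusted p = 0.00779; adjusted p = 0.142 with an estimated correlation), with IAA20 at -2.54. Of 8 autophagy genes 4 fell (median -0.91, adjusted p = 0.000381; adjusted p = 0.164 with an estimated correlation), with ATG8F at -2.07. Tubulins had 2 of 7 higher (median 0.58, and 0.27 without cotyledon dark replicate 1; adjusted p = 0.0123; adjusted p = 0.142 with an estimated correlation), led by TUB7 (AT2G29550) at 2.29 ± 0.23. Of 4 stomata and trichome genes 1 rose, and 3 adjusted over the list alone, without a list call (adjusted p = 0.0748). Chlorophyll synthesis had 1 of 5 genes lower, PORB at -1.56, also 1 adjusted over the list alone, and its median of 0.06 and mean of -0.05 differed in sign without a call (adjusted p = 0.838). The leaf primordium list had 1 of 4 genes higher, also 1 adjusted over the list alone, with a median of -0.44 and a test direction above 0 (adjusted p = 0.931). Chloroplast genome transcripts had 0 calls by limma in the cotyledon (median -0.27, adjusted p = 0.34).

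After 6 h in the cotyledon 2829 probe sets were called, 1420 higher and 1409 lower, and 2497 changed at least 2-fold. The count was 1616 without cotyledon dark replicate 1 and 1647 without cotyledon 6 h replicate 2.

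After 24 to 72 h of light in the apex, most measured photosynthesis genes were higher on the mean of the 3 arrays. OLEO3, ICL and most measured tubulins were lower, while no list was called with an estimated correlation. The late seedlings were also older than the dark ones, so these changes cannot be assigned to light rather than age. THI2.2 was 7.40 ± 0.44 above the dark level (adjusted p = 2.58e-07, 3 late arrays and 2 dark arrays; 7.09 with dim values raised), AT5G43450 was at least 19.6-fold higher and AT1G60590 at least 10.9-fold. The oleosin gene OLEO3 (AT5G51210), which codes for an oil-body protein, was at least 51.9-fold lower, and ICL fell by 4.04 ± 0.31. On the single arrays the ICL change was -6.044 at 24 h, -3.914 at 48 h and -2.155 at 72 h. With dim values raised, IAA20 fell by 3.71 (adjusted p = 3.76e-07), since its signals at 24 and 48 h, 4.32 and 2.11, lay below the floor, and it measured 22.7 at 72 h. AT5G44440 fell by 5.91 ± 0.31, or by 5.00 with dim values raised, AT2G34020 was at least 23.9-fold lower and SUFE2 (AT1G67810), which acts in iron-sulfur cluster assembly, at least 10-fold lower. Some early falls had reversed in part or in full on the single late arrays, while that of AT5G02580 lasted, at least 14.7-fold lower in late light. AT2G32150 rose from its early low to signals of 1694, 2404 and 3408 at 24, 48 and 72 h, still below its dark mean. AT1G19530, with a signal of 895 in the dark and 1.48 after 6 h, reached 26.1, 429 and 1683 at those times.

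Of the 6 photosynthesis genes 5 rose in late light, also 5 adjusted over the list alone (median 1.24, adjusted p = 0.000415; adjusted p = 0.32 with an estimated correlation), and 8 of 11 on the extended list (median 1.16, adjusted p = 1.91e-05; adjusted p = 0.336 with an estimated correlation). LHCB4.2 rose by 1.46, PSAN by 1.72 and PSAE-1 (AT4G28750) by 1.47, while PORB, the single call among chlorophyll synthesis genes both over all probe sets and adjusted over the list alone, fell by 3.00. That list had a median of 0.06 and a mean of -0.50 (adjusted p = 0.52). All 3 flavonoid genes rose, also 3 adjusted over the list alone (median 2.38, adjusted p = 0.0014; adjusted p = 0.121 with an estimated correlation). Of the 5 auxin-response genes 3 fell and 1 rose, also adjusted over the list alone (median -2.35, adjusted p = 0.0186; adjusted p = 0.281 with an estimated correlation). Of 7 tubulins 5 fell and 1 rose (median -1.45, adjusted p = 0.0014; adjusted p = 0.121 with an estimated correlation). TUB1 (AT1G75780) fell by 3.27 ± 0.27 and TUA1 (AT1G64740) rose by 1.52. YAB5 was 1.16 ± 0.27 above the dark level (adjusted p = 0.0109), a call lost without apex dark replicate 2 (0.91, adjusted p = 0.125), and was the single call among 4 leaf primordium genes, also adjusted over the list alone (list adjusted p = 0.179). The stress zinc-finger gene STZ (AT1G27730), the single measured gene of the wounding list, was 3.40 ± 0.93 above the dark level (adjusted p = 0.0237), with signals of 73.1, 244 and 614 at 24, 48 and 72 h. That call was lost without either dark array or the 72 h array (highest adjusted p = 0.145).

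Other list calls in late light depended on single arrays. The ribosomal family had 8 of 113 genes higher (median 0.25, adjusted p = 0.0186; adjusted p = 0.749 with an estimated correlation), lost without apex dark replicate 1 or the 72 h array (highest adjusted p = 0.104). The extended nucleolus list (3 of 22 higher, median 0.55, adjusted p = 0.0203; adjusted p = 0.6 with an estimated correlation) was lost without the same arrays (highest adjusted p = 0.116). The extended mitosis list (4 of 11 higher, median 0.48, adjusted p = 0.0186; adjusted p = 0.32 with an estimated correlation) was lost without the 24 h array (adjusted p = 0.0578). Autophagy (3 of 8 lower, median -0.38, adjusted p = 0.0205; adjusted p = 0.389 with an estimated correlation) was lost without apex dark replicate 2 (adjusted p = 0.134). Chloroplast genome transcripts (3 of 69 lower, median -0.77, adjusted p = 3.42e-05; adjusted p = 0.646 with an estimated correlation) were lost without that array as well, at a median of -0.13.

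In late light 2740 probe sets were called, 1570 higher and 1170 lower, and 1470 without apex dark replicate 2. The single arrays gave 1905 calls at 2 h, 1494 at 24 h, 1365 at 48 h and 1623 at 72 h, from 1 array each, and without apex dark replicate 2 these counts were 1091, 890, 853 and 1017. The median of the flavonoid list was 2.70 at 24 h (adjusted p = 0.000326; adjusted p = 0.128 with an estimated correlation), 2.66 at 48 h (adjusted p = 0.00166; adjusted p = 0.144 with an estimated correlation) and 1.43 at 72 h (adjusted p = 0.0423; adjusted p = 0.445 with an estimated correlation).

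**Figure D3:**
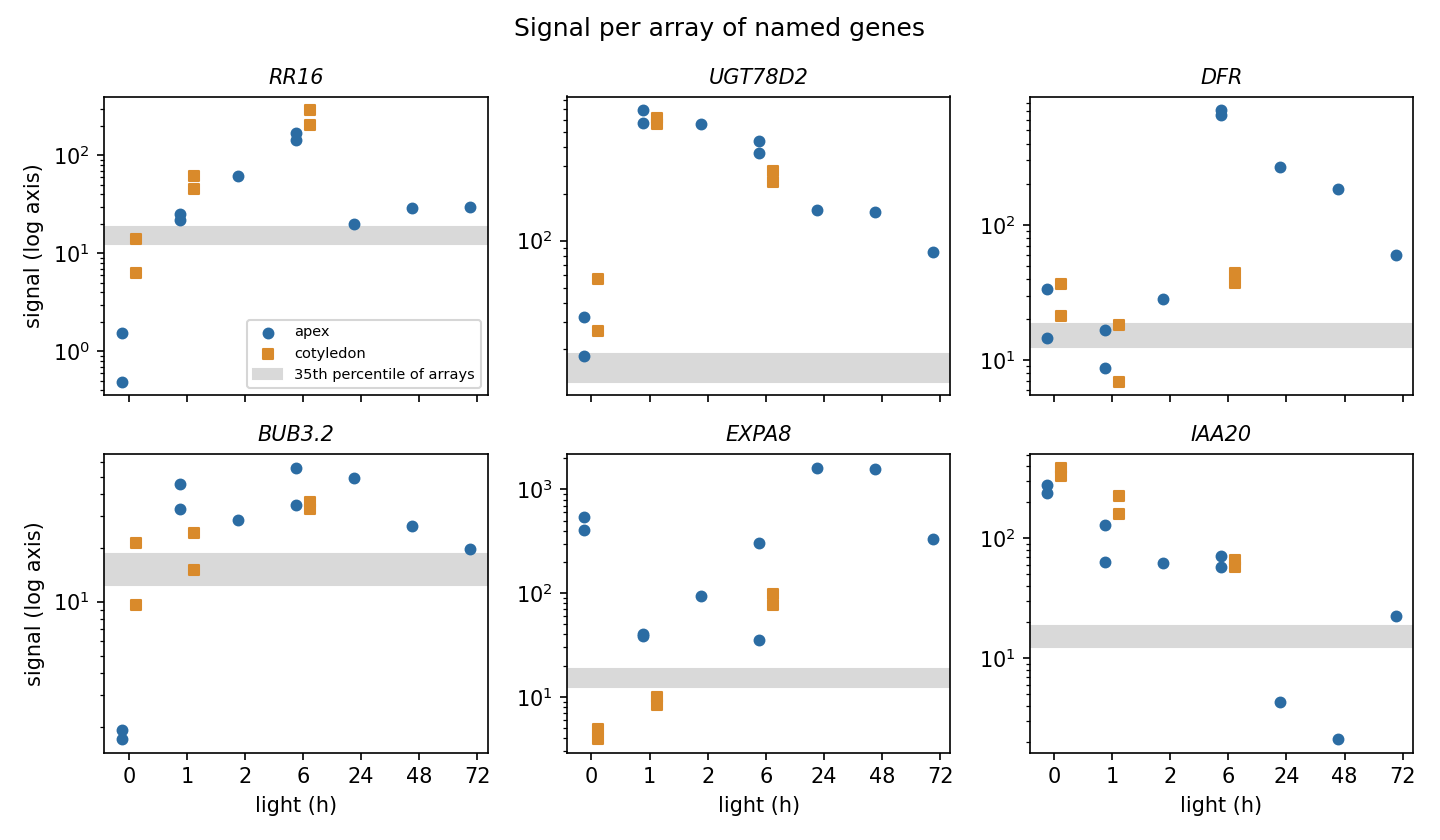
Signal on a log axis per array against hours of light for 6 genes, with apex and cotyledon arrays as separate points, time as evenly spaced categories and the range of the arrays' 35th percentiles as a grey band. DFR rose from a mean of 24.3 to 677.5 in the apex after 6 h and measured 40.9 in the cotyledon.

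In the dark the apex had more transcript than the cotyledon of most measured tubulins and some expansins. It had less of most measured ribosomal protein and chlorophyll synthesis genes. EXPA8 was at least 30.2-fold higher in the apex, the expansin-like genes EXLA1 (AT3G45970) and EXLA2 (AT4G38400) at least 16.5-fold and 4.01-fold, and the bZIP gene BZIP61 (AT3G58120) at least 21.2-fold. AT1G62480 was 7.52 ± 0.68 higher (adjusted p = 1.22e-05, n = 2 arrays per group; 6.07 with dim values raised), AT1G12080 was 6.84 ± 0.59 higher and the auxin-conjugating gene GH3.17 (AT1G28130) at least 5.68-fold. AT5G66985 was at least 10.3-fold lower in the apex, AT1G48660, of the same gene family as GH3.17, at least 9.29-fold and the defensin gene LCR67 (AT1G75830) at least 5.45-fold.

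Of 7 tubulins 6 were higher in the dark apex (median 1.29, adjusted p = 1.07e-06), with TUB1 at 4.49 ± 0.30. This list call was the single one of 70 that held with an estimated correlation (adjusted p = 0.0375). Of 21 expansins and xyloglucan endotransglucosylases 7 were higher (median 0.71, adjusted p = 0.0125; adjusted p = 0.138 with an estimated correlation). Of 5 auxin-response genes 3 were higher, also 3 adjusted over the list alone (median 1.45, adjusted p = 0.0308; adjusted p = 0.175 with an estimated correlation), a call lost without apex dark replicate 1 or cotyledon dark replicate 2 (highest adjusted p = 0.0724). IAA29 was 4.55 ± 0.51 higher, or 4.21 with dim values raised. Autophagy had 3 of 8 genes higher (median 0.49, adjusted p = 0.0371; adjusted p = 0.441 with an estimated correlation), lost without apex dark replicate 2 or cotyledon dark replicate 2 (highest adjusted p = 0.242).

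In the ribosomal family 72 of 113 genes were lower in the dark apex (median -1.04, adjusted p = 4.78e-27; adjusted p = 0.171 with an estimated correlation). The fixed ribosomal list had 2 of 4 lower, and 3 adjusted over the list alone (median -0.87, adjusted p = 0.0308; adjusted p = 0.441 with an estimated correlation), lost with quantile normalization (adjusted p = 0.271) and without apex dark replicate 2 or cotyledon dark replicate 2 (highest adjusted p = 0.0929). Of 9 plastid ribosomal protein genes 8 were lower (median -1.54, adjusted p = 1.32e-08; adjusted p = 0.171 with an estimated correlation). Of 5 chlorophyll synthesis genes 3 were lower, also 3 adjusted over the list alone (median -1.81, adjusted p = 0.000268; adjusted p = 0.125 with an estimated correlation), with HEMB1 (AT1G69740), an enzyme of porphyrin synthesis, at -1.98 ± 0.24. Nuclear photosynthesis genes on the extended list had 3 of 11 lower (median -0.74, adjusted p = 0.00326; adjusted p = 0.441 with an estimated correlation), and quantile normalization ended that call (adjusted p = 0.28). The GAPDH 3' to 5' ratio also differed between these groups, at 0.90 and 1.78 in the dark apex and 4.72 and 2.60 in the dark cotyledon. The meristem genes CLV3 and LAS were not called in this or any other of the main contrasts, and CLV3 measured 2.03 (adjusted p = 0.229).

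Between the dark tissues 3077 probe sets were called, 1553 higher and 1524 lower in the apex, so that 50.47% of calls were higher. Median centring shifted the median of all probe sets by -0.23 and lowered that share to 34.49%, quantile normalization shifted it by -0.11, and leaving out cotyledon dark replicate 1 or apex dark replicate 2 lowered the count to 1769 or 1805. Calls were 853 higher and 1200 lower without apex dark replicate 1 and 1144 higher and 914 lower without cotyledon dark replicate 2.

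The light responses of the tissues overlapped more than independent calls would. After 1 h 164 probe sets were higher in both, against 15.7 with independence, and 89 were lower in both, against 6.3, while 4 that were lower in the apex were higher in the cotyledon. After 6 h 858 were higher and 825 lower in both, against 175 and 181.3, while 17 were higher in the apex and lower in the cotyledon and 28 the reverse. The correlation of the changes across genes, which are not independent replicates, was 0.26 after 1 h and 0.50 after 6 h. The apex and cotyledon responses share no arrays, but the fit gave both the same spread for each probe set. Calls can therefore coincide without a shared response, and the counts with independence are only a reference.

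Tissue differences in the response to 1 h of light were called for whole lists more than for their members, and no list call held with an estimated correlation. The ribosomal family's change was higher in the apex by a median of 0.77 (adjusted p = 2.14e-16; adjusted p = 0.35 with an estimated correlation), with 0 of 113 genes called one by one by limma. The fixed mitosis list differed by 1.24 (adjusted p = 0.0134; adjusted p = 0.248 with an estimated correlation) with 1 of 3 genes called, also 1 adjusted over the list alone. The extended mitosis list differed by 1.24 (adjusted p = 0.000211; adjusted p = 0.248 with an estimated correlation) with 2 of 11 called, and autophagy by -1.18 (adjusted p = 0.000178; adjusted p = 0.248 with an estimated correlation) with 1 of 8 called. Of single genes, the change of AT2G32150 differed by -7.44 ± 1.13 (adjusted p = 0.00619), with cotyledon signals of 93 in the dark and 209 after 1 h. The cell wall gene XTH32 (AT2G36870) had a change higher in the apex by 2.52 (adjusted p = 0.00679). The change of AT3G21670 differed by -5.57. Its dark signal was 224 in the apex and 4.35 in the cotyledon, below the floor, and with dim values raised to the floor the difference was -3.49 (adjusted p = 0.00393). With a variance prior without trend these 3 genes were not called (adjusted p = 0.117 for AT2G32150, 0.0977 for XTH32 and 0.0911 for AT3G21670).

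The extended nucleolus list (0.77, adjusted p = 0.00828; adjusted p = 0.535 with an estimated correlation) was also called higher in the apex after 1 h, but not without cotyledon dark replicate 2 or cotyledon 1 h replicate 1 (highest adjusted p = 0.244). Plastid ribosomal proteins (0.59, adjusted p = 0.025; adjusted p = 0.535 with an estimated correlation) lost the call without apex dark replicate 2, apex 1 h replicate 2, cotyledon dark replicate 1 or cotyledon 1 h replicate 2 (highest adjusted p = 0.305). Core histones (0.81, adjusted p = 0.0444; adjusted p = 0.248 with an estimated correlation) lost it with log2(value + 16) (adjusted p = 0.0513), with raised values (adjusted p = 0.0817) and without apex dark replicate 2, apex 1 h replicate 2, cotyledon dark replicate 2 or either cotyledon 1 h array (highest adjusted p = 0.253). These 3 lists had 0 members called by limma.

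The number of probe sets with a different light response was 186 after 1 h, 48 higher and 138 lower in the apex, against 2548 at an unadjusted p under 0.05. It was 15 with a variance prior without trend. Leaving out apex dark replicate 2, either apex 1 h array, either cotyledon dark array or cotyledon 1 h replicate 1 gave between 64 and 111. The balance of higher and lower calls rested on single arrays, with 127 higher and 101 lower without apex dark replicate 1 and 128 higher and 155 lower, 283 in total, without cotyledon 1 h replicate 2.

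**Figure D4:**
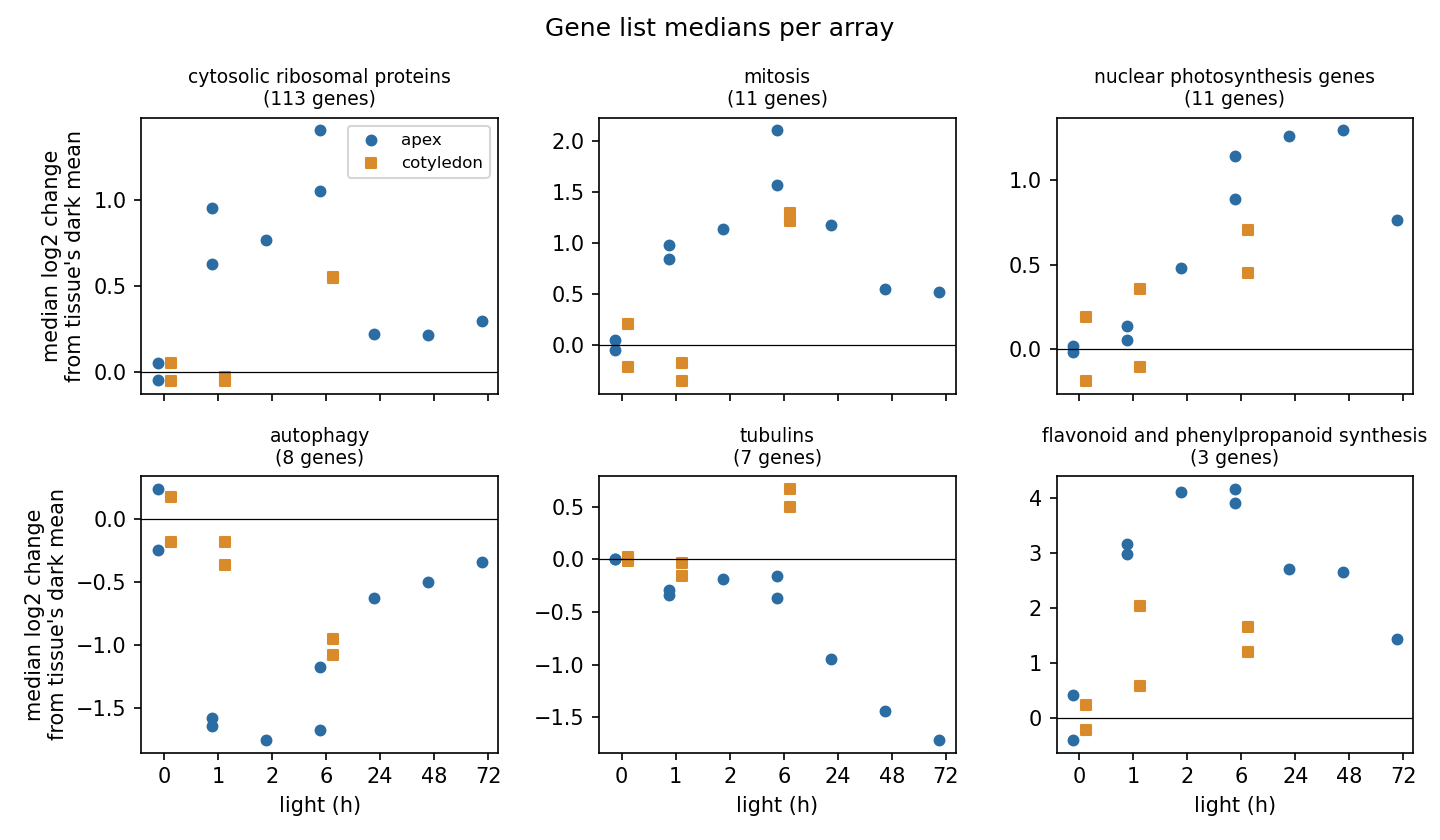
Median log2 change of 6 gene lists on each array (y axis) relative to the dark mean of the same tissue, against hours of light as evenly spaced categories (x axis), with apex arrays as circles and cotyledon arrays as squares. The medians of the 113 ribosomal protein genes were 0.63 and 0.95 on the apex arrays and -0.03 and -0.06 on the cotyledon arrays after 1 h.

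After 6 h the change of the flavonoid list was higher in the apex by a median of 2.14 (adjusted p = 0.00113; adjusted p = 0.12 with an estimated correlation), with 1 of 3 called and 3 adjusted over the list alone. The gene called was DFR, whose change was higher in the apex by 4.37 ± 0.75 (adjusted p = 0.00877). The change of AT1G48660, below the floor in the dark apex, was higher in the apex by 7.40 ± 0.82 (adjusted p = 0.00119), and by 4.86 with dim values raised (adjusted p = 0.000237). EXPA8, below the floor in the dark cotyledon and higher there after 6 h, differed by -6.48 ± 0.94 (adjusted p = 0.00417), and by -4.65 with dim values raised (adjusted p = 0.00581). Its apex signals after 6 h disagreed, at 306.2 in replicate 1 and 35.13 in replicate 2, the array with the GAPDH ratio of 5.40. With a variance prior without trend DFR (adjusted p = 0.0745) and EXPA8 (adjusted p = 0.0671) were not called. The ribosomal family differed by 0.68, and by 0.44 without apex 6 h replicate 2 (adjusted p = 8.67e-11; adjusted p = 0.514 with an estimated correlation) with 1 of 113 called, and plastid ribosomal proteins by 0.74 (adjusted p = 0.000325; adjusted p = 0.514 with an estimated correlation) with 2 of 9 called. Tubulins differed by -1.03 (adjusted p = 0.00165; adjusted p = 0.12 with an estimated correlation) with 1 of 7 called. Chloroplast genome transcripts differed by -1.13 (adjusted p = 8.86e-06; adjusted p = 0.801 with an estimated correlation) with 0 of 69 called by limma, and the call was lost without apex dark replicate 2 or apex 6 h replicate 2 (highest adjusted p = 0.458). The RNA-quality ratio of apex 6 h replicate 2 applies to this contrast as well.

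After 6 h 490 probe sets differed in their light response, 228 higher and 262 lower in the apex. The count was 14 with a variance prior without trend, 311 without apex dark replicate 1, with 193 higher and 118 lower, 130 without both arrays that stood apart and 1137 without apex 6 h replicate 1, and leaving out any other single array of the compared groups gave between 153 and 323. Median centring shifted the median of all probe sets by 0.13. These differences and the tissue comparison in the dark share the dark arrays.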

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

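Tests chosen only after the result was seen were that of the ribosomal level before light and those on the number of calls after 1 h.

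Light responses that differed between apex and cotyledon drew attention, and 3 patterns were weighed. As a list, ribosomal protein genes were called with a higher change in the apex than in the cotyledon after 1 h, by a median of 0.768 (adjusted p = 0.35 with an estimated correlation), with 0 of 113 genes called one by one by limma. The tables argue against a single dark apex array as the cause, since the median was 0.806 without dark apex replicate 2 and 0.75 without replicate 1, and against scaling, since it was 0.782 after quantile normalization. With any 1 of the 8 arrays left out the median lay between 0.631 and 0.939. A lower starting level in the dark apex cannot be told apart from a different response to light, because the median difference of -0.264 after 1 h follows from the dark difference and the difference in response and decides nothing. Which biological property of the tissues would produce the difference was not tested and stays open.

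Chloroplast genome transcripts were called lower as a list in the apex after 6 h of light (adjusted p = 0.506 with an estimated correlation), with 16 of 69 called one by one. Scaling is argued against, with a median of -1.414 after quantile normalization. The RNA of apex 6 h replicate 2, the array with the highest 3' to 5' ratios, could account for much of it, since the median was -0.4 without that array, and with a single 6 h array left this cannot be told apart from a fall caused by light. Dark apex replicate 2 also stays open, with a median of -0.783 without it.

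More probe sets were called after 1 h in the apex than in the cotyledon. A single apex array is not the cause of the difference, since the lowest apex count with 1 of the 4 arrays left out was 722, above the full cotyledon count of 399. The ratio between the cotyledon and apex differences between replicates was 1.066. That ratio does not bear on the count, because the fit gave both tissues the same spread for each probe set. The median standard error was 0.4175 in both contrasts. This argues against tighter apex replicates as the cause, since they could not give the apex smaller standard errors. A stronger early response of the apex stays a hypothesis found and tested on the same data, and the difference itself was called for 186 probe sets.

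After 1 h the other lists called for a different response between the tissues were mitosis and cytokinesis (1.242), the extended mitosis list (1.242), the extended nucleolus list (0.765), plastid ribosomal proteins (0.587), core histones (0.811) and autophagy (-1.181), all lost with an estimated correlation (adjusted p = 0.248 with an estimated correlation for mitosis, histones and autophagy and 0.535 for the others). The fixed and extended mitosis lists share members, so their calls are not independent. The nucleolus, plastid and histone calls were also lost without single arrays and had 0 members called by limma. After 6 h they were flavonoid synthesis (2.139), the ribosomal family (0.677), plastid ribosomal proteins (0.743), chloroplast genome transcripts (-1.129) and tubulins (-1.031), all lost as well (adjusted p = 0.12 with an estimated correlation for flavonoids and tubulins, 0.514 for the ribosomal lists and 0.801 for the chloroplast genome). The chloroplast call was also lost without apex dark replicate 2 or apex 6 h replicate 2. The numbers of probe sets with a different response were 186 after 1 h and 490 after 6 h.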

How the results depend on the processing

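Leaving out both arrays that stood apart was chosen only after the results were seen. Raising dim values, and leaving out single arrays in the list tests, were also not planned in advance. Counts not named here stayed within 1.5 times the reported ones with median centring, either filter, arrays of the compared tissue alone, raised dim values, a replicate block and a 2-fold minimum, as far as each was run. A variance prior without trend lowered the counts to 1016 (apex 1 h), 190 (cotyledon 1 h), 15 and 14 (tissue difference at 1 h and 6 h), 1012 (apex 2 h), 845 (24 h), 828 (48 h) and 983 (72 h), and the cause was not tested. The tissue difference at 1 h gave 294 calls with quantile normalization and 286 with log2(value + 16), and the cause was not tested. Without both arrays that stood apart, apex 6 h gave 2316 and the tissue difference at 6 h 130, with fewer samples. Leaving out 1 array at a time gave 722 to 1339 (apex 1 h), 2846 to 4357 (apex 6 h), 202 to 368 (cotyledon 1 h), 1616 to 1961 (cotyledon 6 h), 1470 to 2346 (late), 1769 to 2058 (dark tissues), 64 to 283 and 153 to 1137 (tissue difference at 1 h and 6 h), 1091 to 1479 (2 h), 890 to 1202 (24 h), 853 to 1165 (48 h) and 1017 to 1276 (72 h). The counts furthest from the full set were those without apex dark replicate 2 for apex 6 h, late light and the single times, apex 1 h replicate 2 for apex 1 h and the tissue difference at 1 h, cotyledon dark replicate 1 for the cotyledon and the dark tissues, and apex 6 h replicate 1 (1137) and cotyledon 6 h replicate 1 (153) for the tissue difference at 6 h. Where an arm kept 1 array, it was assumed to vary like the other groups, and a single-array comparison without its own array gives no value. Calls of lists went from 70 of 184 to 1 with an estimated correlation, and were 64 with quantile normalization, 71 with log2(value + 16) and 75 with raised dim values. The version with an estimated correlation also uses 6 residual degrees of freedom, so a lost call need not reflect correlated genes. The flavonoid and fixed mitosis lists lost their calls at estimates of -0.1601 and -0.1837. With a replicate block the counts were 1862, 4473, 387, 2740, 2333, 2966, 186 and 458 in the order apex 1 h, apex 6 h, cotyledon 1 h, cotyledon 6 h, late, dark tissues and the tissue difference at 1 h and 6 h, with 72 list calls. Replicate numbers did not pair the arrays, with correlations of replicate differences from -0.128 to 0.125 over 15 pairs of groups, 1 of them above 0.1.

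Of 356 calls among 861 values of named genes, 99 were lost without the variance trend, 27 with raised dim values, 28 with arrays of the compared tissue alone, 10 with median centring, 8 with quantile normalization, 8 with log2(value + 16) and 9 without a filter, and with 1 array left out 443 values lost the call and 1190 kept it. RR16 and MUTE, lower in the dark apex as reported, reversed to 0.074 each with raised dim values, since both groups lay at or below the floor there. Signal over background limits all comparisons with dim probe sets, whose folds are bounds.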

Other observations

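No test in this part was chosen after its result was seen, but the check with raised dim values was not planned in advance. Genes of other lists gave further values. The sugar transporter gene SWEET2 (AT3G14770) was 3.77 above the dark level in the late apex, where SWEET17 (AT4G15920), a fructose transporter gene, was 2.76 higher, and 4.01 above it in the cotyledon after 6 h. The SWEET list was not called in any main contrast, with 2 of 14 genes higher and 1 lower in late light (adjusted p = 0.319). Tau-class glutathione transferases, which conjugate glutathione to small molecules, had 4 of 8 genes higher and 1 lower in late light without a list call (adjusted p = 0.195), and GSTU26 (AT1G17190) fell by 2.31. UDP-glycosyltransferases had 5 of 32 genes higher and 2 lower in the cotyledon after 6 h (adjusted p = 0.721), and UGT71C4 (AT1G07250) was 1.83 higher there after 1 h. XTH32, a xyloglucan endotransglucosylase gene, rose in the apex by 3.39 after 1 h, 3.90 after 6 h and 2.18 in late light, while EXPA4 (AT2G39700) fell by 2.45 after 6 h and 2.93 in late light.

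EXPA8 went from a signal of 475.6 ± 98.5 (SD) in the dark apex to 39.8 ± 1.29 after 1 h and 93.49 on the single array after 2 h. It measured 306.2 and 35.13 in replicates 1 and 2 after 6 h, and stood at 1629, 1564 and 333 on the single arrays at 24, 48 and 72 h. TUB1 went from 721 in the dark to 231, 86.1 and 21 at those times. The leaf primordium gene JAG (AT1G68480), a regulator of blade growth, had signals of 8.51 ± 3.58 in the dark and 26.7, 40.9 and 49 at 24, 48 and 72 h, without a call in late light (adjusted p = 0.171). The extended DNA replication list had 0 of 5 genes called by limma in each main contrast, and its smallest adjusted p was 0.123, in the cotyledon after 6 h. The DNA replication genes ICU2 and PRL and the gibberellin receptor genes GID1A and GID1B were not called in any main contrast. The root-list gene EXPA18 was called lower in the apex after 6 h (adjusted p = 0.00926) and lost the call without either dark array or apex 6 h replicate 1. Of the cytokinin-response genes, RR16 was at least 15.6-fold higher in the cotyledon after 6 h, and ARR15 was called in the apex after 1 h (3.59, adjusted p = 0.0433), a call that ended with raised dim values (0.39). The median, mean or test direction of a list also differed in sign for tubulins in the cotyledon after 1 h, for core histones and expansins in late light, for the leaf primordium, stomata and SWEET lists between the dark tissues, and for the auxin, expansin, tubulin, SWEET, histone and UDP-glycosyltransferase lists in the tissue differences, in each case without a list call.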
